A study of Homo sapiens with 12 samples.

How the data were processed

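The series holds 12 arrays of total RNA from sorted human chordoma cells of 3 lines, JHC7, U1 and MUG-CHOR1, with 2 duplicate sorts of CD133+CD15+ and of CD133-CD15- cells per line. Per the labels, cells were grown in a mix of IMDM and RPMI with fetal bovine serum, RNA was extracted with Trizol, and 500 ng per array was labelled as cDNA by a whole-transcript protocol. The labels name Transcriptome Analysis Console, without a version, as the tool. The deposited values are log2 values, 1 per probe set and array for 53617 probe sets. The authors' summarization, background correction and normalization are not given in the sources used here. The base of the logarithm was read from the range of the values, -0.20 to 12.5, and the columns had not been forced to 1 common distribution, so the deposited values were used as they are.

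Of the probe sets, 23871 carried exactly 1 gene symbol, 1842 several and 27904 none. By Entrez identifier 22569 were matched to the reference gene table, and 90 symbols were updated. A gene with more than 1 probe set (632 genes) was represented by the probe set with the highest mean over the 12 arrays, which left 22395 genes, with no filter on level. Positions of probe sets on a genome build are not given in the sources used here, so genes are given by symbol, Entrez Gene number and chromosome. Probe sets with no or several symbols were left out of the comparisons and tested apart. Duplicates were checked for identical columns and none were found.

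The fit used limma 3.58.1 in R 4.3.3, with 1 mean per line and sort (6 means), empirical Bayes moderation with a variance trend, 6 residual and 7.4 prior degrees of freedom, and two-sided tests adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. The comparisons were the mean over lines of the difference CD133+CD15+ minus CD133-CD15-, the same difference within each line, an F test of whether that difference varies between lines, and an F test between lines. The effect of each line is thus removed from the comparison of sorts, and the result holds for these 3 lines. Errors are standard errors of the fit. The duplicate numbers were not used to pair arrays, since the deviations of arrays with the same number correlated at -0.16 in JHC7, 0.07 in U1 and -0.02 in MUG-CHOR1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

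The comparisons, their tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Gene lists of at least 5 measured genes (39 lists) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and beside it with camera at an estimated correlation and with fry. They covered sort antigens and CD15 fucosylation, notochord and chordoma markers, cartilage matrix, pluripotency and stem cell factors, drug transporters, epithelial and mesenchymal genes, G1/S and G2/M genes, p53 targets, hypoxia and glycolysis, nuclear and mitochondrially encoded respiratory genes, ribosomal proteins, type I interferon, NF-kB, antigen presentation, the unfolded protein, amino acid starvation and heat shock responses, cholesterol biosynthesis, and the Notch, Wnt, Hedgehog, TGF-beta and BMP, and receptor tyrosine kinase pathways. They also covered apoptosis regulators, histones, small nucleolar RNAs, microRNAs, olfactory receptors, housekeeping genes, and markers of fibroblasts, macrophages and monocytes, granulocytes, lymphocytes, endothelium, erythroid cells and neural lineages. The mitochondrially encoded genes were matched under their reference names as well after the values were seen, which raised their number to 8.

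Named genes were PROM1, FUT4 and TBXT always. Across lines, they were the up to 12 largest rises and 12 largest falls among genes past the threshold with the same direction in all 3 lines. Within each line, they were the 5 largest rises and falls past the threshold. For the difference between lines of the sort effect they were the 6 genes with the smallest p, between lines the 5 with the largest excess in each line, and per list up to 4 members with the smallest p. Genes of small nucleolar RNAs, microRNAs, olfactory receptors and the sex-specific genes were not named by rank. Any other gene is said to have been chosen after its values were seen.

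The procedure was tested on simulated data of 22395 genes with the design of the series. Of 50 genes changed by 1, 2, 3 or 4 (log2), the comparison across lines recovered 25, 47, 50 and 50, and that within 1 line 5, 36, 42 and 49. Of 177 genes called across lines 5 were unchanged. Of 40 simulated lists, the 10 shifted ones were called and none of the 30 others. The simulated genes varied independently, and each had the same spread on all arrays. These rates therefore do not carry over to correlated lists or to arrays of unequal spread.

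The alternative settings were quantile normalization, centring on the median, genes above the median level, every named probe set, all probe sets, the mean of the probe sets of a gene, a variance without a trend, a robust variance, array weights, a block of the duplicate numbers within lines, leaving out each array or line, thresholds with a 2-fold change, duplicates averaged to 3 pairs, additive models of line and sort with and without a random block, no line term, and only the 4 arrays of a line. Alternatives chosen after seeing the data left out the second CD133+CD15+ duplicate of every line (also with quantile normalization), or of JHC7 and MUG-CHOR1, scaled each array to the same mean and SD, or crossed the duplicate numbers of JHC7. With the second duplicates left out, 3 CD133+CD15+ arrays stood against 6 CD133-CD15- arrays, with 3 residual and 8.9 prior degrees of freedom. Each lone CD133+CD15+ array was then assumed to vary like the CD133-CD15- groups. The CD133+CD15+ duplicates differed more, with an SD of their difference of 0.77 in JHC7, 0.50 in U1 and 1.04 in MUG-CHOR1. That of the CD133-CD15- duplicates was 0.33, 0.38 and 0.29, so errors from this fit may be too small. Random lists of the same levels were drawn 10000 times, and other splits of the arrays 100 times.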

Results

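RNA levels were measured on 12 whole-transcript arrays of human chordoma cells. Chordoma is a tumour of the notochord lineage. The labels give 3 lines, JHC7, U1 and MUG-CHOR1, and for each line a CD133+CD15+ and a CD133-CD15- population taken by cell sorting. Each population was sorted in duplicate, which made 6 groups of 2 arrays, and the series title calls the CD133+CD15+ cells chordoma cancer stem cells. The duplicates are duplicate sorts of the same line, so every p-value here measures only the spread between these samples. The number of arrays limits the precision.

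The deposited log2 values of the second CD133+CD15+ duplicate of every line were spread more narrowly than those of the other 9 arrays. Their SD over all probe sets was 1.56 in JHC7, 1.56 in U1 and 1.28 in MUG-CHOR1, against 1.70 to 1.83 on the other arrays. They held 1809, 1833 and 949 probe sets above 6 (log2), against 2441 to 3053. Olfactory receptor genes, which these cells are not known to use, had medians of 1.29, 1.24 and 1.52 on these 3 arrays and 1.01 to 1.19 on the others. The first CD133+CD15+ duplicates had SDs of 1.75 in JHC7, 1.70 in U1 and 1.76 in MUG-CHOR1, each below both CD133-CD15- arrays of the line. Across probe sets, which are not independent replicates, the CD133-CD15- duplicates correlated at 0.969 to 0.980 and the CD133+CD15+ duplicates at 0.884 in JHC7, 0.941 in U1 and 0.801 in MUG-CHOR1. Every comparison of the sorts was therefore also run without these 3 narrow arrays.

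**Figure D1:**
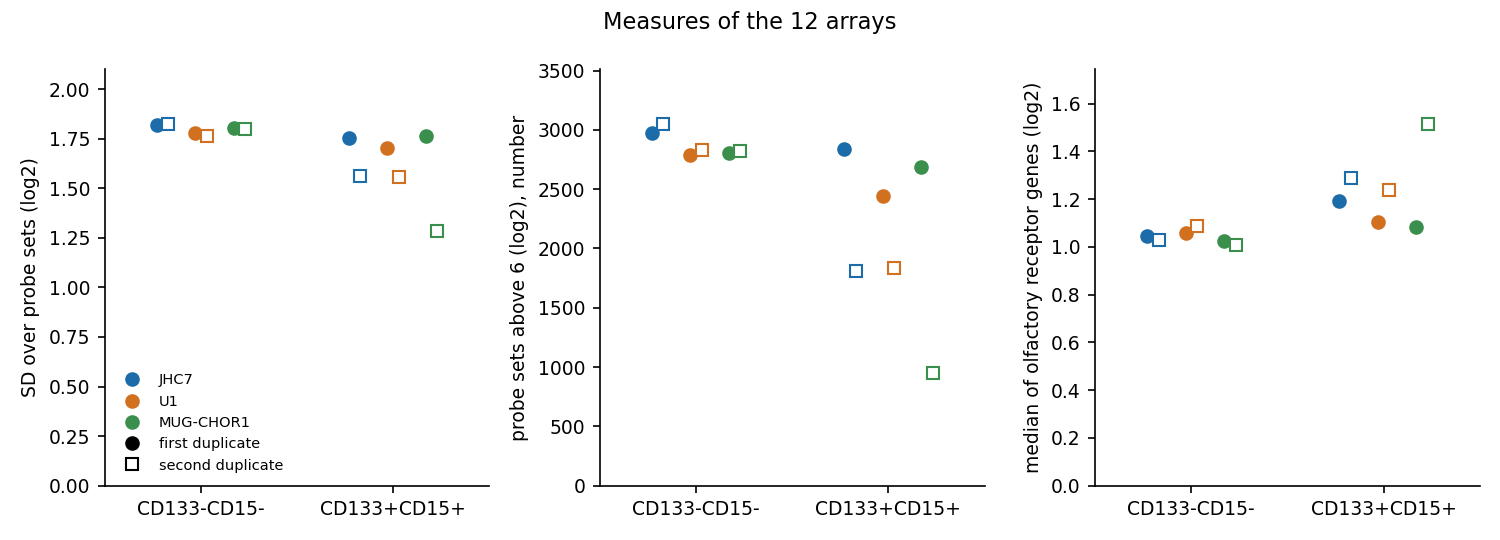
SD over probe sets (log2), number of probe sets above 6 (log2) and median of the olfactory receptor genes (log2) for each of the 12 arrays, by sort, with 1 point per array, coloured by line. The second CD133+CD15+ duplicates (open squares) have the lowest SD, 1.28 to 1.56, and the fewest bright probe sets, 949 to 1833.

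The main question was how CD133+CD15+ cells differ from CD133-CD15- cells of the same line, averaged over the 3 lines. Genes of mitosis were lower in the CD133+CD15+ cells. MKI67, the Ki-67 antigen of cycling cells (Entrez Gene 4288, chromosome 10), fell 4.44-fold (log2 -2.15, SE 0.33, adjusted p = 0.0315, n = 6 and 6 arrays). TPX2 and NUSAP1, which build the mitotic spindle, were 4.98-fold lower (log2 -2.32, SE 0.44, adjusted p = 0.0490) and 4.48-fold lower (log2 -2.17, SE 0.36, adjusted p = 0.0315). The kinetochore genes CENPF and CENPE had log2 differences of -2.16 (SE 0.39) and -2.05 (SE 0.39). The mitotic kinesins KIF20A and KIF11, the spindle gene DLGAP5, CDC20, an activator of the anaphase-promoting complex, and CCNA2, which encodes cyclin A2, fell as well, with log2 differences from -2.05 to -1.83.

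In CD133+CD15+ cells 12 genes were higher across lines. IGFBP5, a binding protein of insulin-like growth factors (Entrez Gene 3488, chromosome 2), was 2.84-fold higher (log2 1.50, SE 0.25, adjusted p = 0.0315). LBP, the lipopolysaccharide-binding protein, was 2.43-fold higher (log2 1.28, SE 0.20), and DLX3, a homeobox gene of bone, tooth and skin development, was 2.41-fold higher (log2 1.27, SE 0.21). The enamel matrix gene AMBN rose by 1.10 (SE 0.17), the small proteoglycan gene DCN by 0.83 (SE 0.13) and the protease inhibitor gene SPINK2 by 0.83 (SE 0.16) on the log2 scale. BEX1, called at 0.96 (SE 0.17), did not go the same way in all 3 lines, with 0.25 in JHC7, 2.81 in U1 and -0.19 in MUG-CHOR1. The other 5 called rises were 5S ribosomal RNA pseudogenes, with RN5S480 at 1.66 (SE 0.30). Of 447 such pseudogenes measured, 353 had a positive difference and 5 passed the test, with a median of 0.22, and without the narrow arrays the median was 0.08 with 16 higher and 3 lower.

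In all, limma called 76 of 22395 genes at an adjusted p under 0.05, 12 higher and 64 lower in CD133+CD15+ cells, and 71 of them moved the same way in all 3 lines. At an unadjusted p under 0.05 there were 5956 genes, 2124 higher and 3832 lower. The named genes were picked on these same arrays by the threshold and the same direction in all 3 lines. Agreement on single arrays therefore follows largely from the choice. Of the named genes, 10 of 11 rises and 11 of 12 falls held on all 6 CD133+CD15+ arrays against the CD133-CD15- mean of their line. DCN was higher on 5 of the 6, and MINAR2, at a log2 difference of -1.99 (SE 0.31), was lower on 5 of the 6. PTCHD1, which encodes a patched-domain membrane protein, fell by 1.90 (SE 0.33) on all 6. Among the 64 lower genes, 24 were on a cell cycle list, of 96 list genes measured (odds ratio 184, two-sided Fisher's exact test p = 1.43e-41, genes not being independent replicates).

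Without the 3 narrow arrays all 76 genes kept their sign, on arrays that had entered the first fit as well. Calls on these remaining arrays may be too many. Their spread comes from the CD133-CD15- duplicates alone, and the CD133+CD15+ duplicates differed more. MKI67 then stood at -1.73, IGFBP5 at 1.43, LBP at 1.28, TPX2 at -1.47, CENPE at -1.33 and KIF11 at -1.28. The mean over lines hides differences there: IGFBP5 was at 3.46 in JHC7, 0.24 in U1 and 0.58 in MUG-CHOR1, AMBN at 2.97, 0.45 and 0.31, and MINAR2 at -2.07, -2.73 and 0.33, and on these arrays the test of a difference between lines passed for these 3 genes and for BEX1. No gene passed in limma after quantile normalization (3767 at an unadjusted p under 0.05), after scaling to the same SD (3831), without a variance trend (5676), without a line term (5133), or without JHC7 (3790), U1 (3029) or MUG-CHOR1 (4299), and several other alternatives moved the count by over 1.5 times. Leaving out 1 array gave 9114 genes without the first CD133+CD15+ duplicate of MUG-CHOR1, 2757 without that of JHC7, 3 without the second of JHC7, and 0 in limma without the second of U1 (3479 at an unadjusted p under 0.05) or without any of the 6 CD133-CD15- arrays (3528 to 4249).

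**Figure D2:**
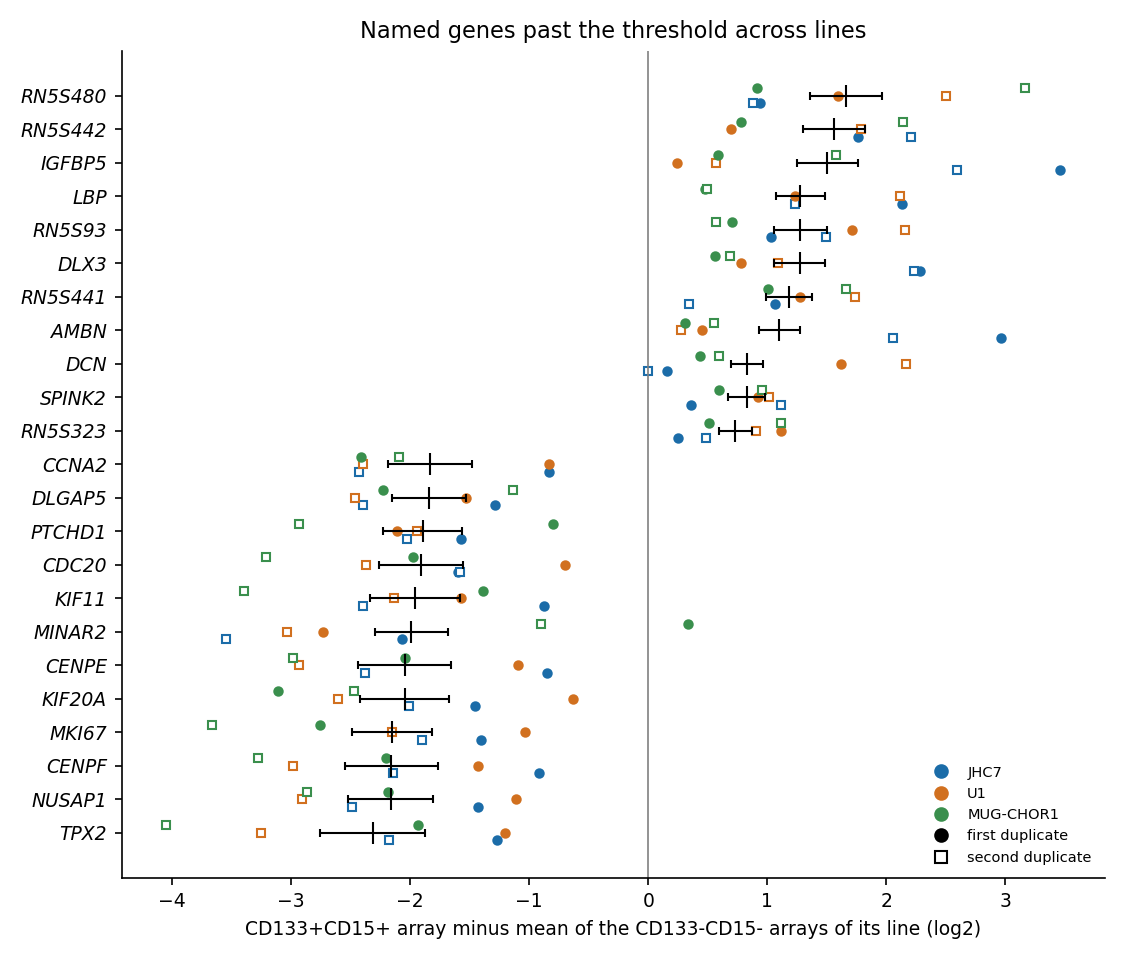
Difference (log2) of each CD133+CD15+ array from the mean of the CD133-CD15- arrays of its line, for the 23 named genes past the threshold across lines. Filled circles are first and open squares second duplicates, coloured by line, and black bars are the mean over lines with its SE, as for MKI67 at -2.15 and IGFBP5 at 1.50.

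PROM1, which encodes CD133 (Entrez Gene 8842, chromosome 4), and FUT4, which encodes a fucosyltransferase that makes the CD15 carbohydrate (Entrez Gene 2526, chromosome 11), did not pass the test between the sorts. PROM1 differed by 0.30 (log2, SE 0.16, adjusted p = 0.230, n = 6 and 6 arrays) and lay between 1.46 and 2.53 on the 12 arrays, at percentiles 71.8 to 93.9 of the olfactory receptor genes. FUT4 differed by 0.26 (SE 0.19, adjusted p = 0.352) and lay at percentiles 82.7 to 99.2. None of the 13 measured genes of the list of sort antigens and CD15 fucosylation passed, also when adjusted over the list alone, and the median was 0.19. TBXT, which encodes brachyury, the transcription factor of the notochord and of chordoma (Entrez Gene 6862, chromosome 6), was high in all groups, at 6.75 to 8.89. TBXT differed by -1.03 (SE 0.33, adjusted p = 0.138) and did not pass with all arrays. Levels as low as those of PROM1 cannot show whether the transcript differed. Without the 3 narrow arrays PROM1 differed by 0.13 and FUT4 by 0.10, and TBXT by -0.69, which then passed the test.

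Both lists of cell cycle genes moved down as groups across lines. Of 54 G2/M genes measured, 54 were lower, with a median of -1.30 (camera, adjusted p = 5.25e-29), and 20 fell over all genes tested, 50 when adjusted over the list alone. HMMR, a spindle-associated gene, was at -1.47 (SE 0.22) and KIF20B, a mitotic kinesin, at -1.48 (SE 0.24), beside MKI67 and NUSAP1. Of 42 G1/S genes, 42 were lower, with a median of -1.03 (adjusted p = 5.29e-17), and 4 fell, 33 when adjusted over the list alone: WDR76 at -1.73, BRIP1 at -1.59, EXO1 at -1.14 and RAD51AP1 at -1.09, the last 3 being DNA repair genes. Neither list passed camera with an estimated correlation (adjusted p = 0.524 with an estimated correlation for each, the highest over their alternatives, which began at 8.67e-41 for G2/M and 1.14e-19 for G1/S), and fry gave an adjusted p of 0.0311 for G2/M and 0.0492 for G1/S.

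The G2/M median was negative in each line, at -1.42 in JHC7, -1.17 in U1 and -1.46 in MUG-CHOR1, and so was the G1/S median, at -1.07, -0.68 and -0.96. The mean of the G2/M list differed from the CD133-CD15- arrays of the line by -1.13 to -0.75 on the first duplicates and by -1.75 to -1.63 on the narrow second duplicates. Housekeeping genes moved with it, by -0.36 to -0.11 on the first and by -2.03 to -0.63 on the second. Both cell cycle medians stayed negative under every scaling of the arrays. Without the narrow arrays they were -0.997 with 54 of 54 G2/M genes lower and -0.62 with 41 of 42 G1/S genes lower.

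**Figure D3:**
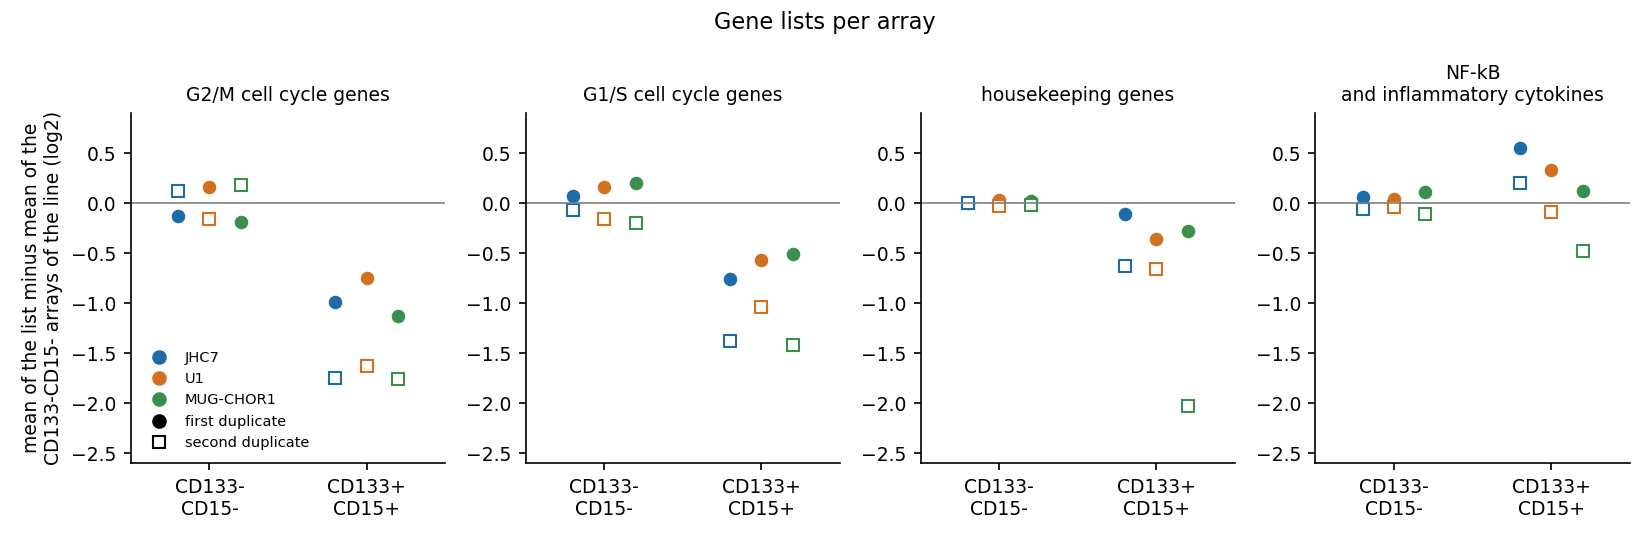
Mean of 4 gene lists on each array minus the mean of the CD133-CD15- arrays of its line (log2), by sort, with 1 point per array, coloured by line. G2/M genes lie at -1.13 to -0.75 on the first CD133+CD15+ duplicates and at -1.75 to -1.63 on the second, while housekeeping genes lie at -0.36 to -0.11 and -2.03 to -0.63.

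In camera with the preset correlation 13 other lists passed across lines, none of which passed with an estimated correlation (smallest adjusted p = 0.524 with an estimated correlation over the 39 lists). Lower medians were found for cholesterol biosynthesis (-0.60, 19 genes, all lower, none called, 5 when adjusted over the list alone, STARD4 at -1.28), housekeeping genes (-0.78, 1 over the list alone), nuclear-encoded oxidative phosphorylation (-0.40) and cytosolic ribosomal proteins (-0.32), with no member called of the last 2, also when adjusted over the list alone. The median was -0.49 for notochord and chordoma markers, 0.05 after scaling to the same SD, with TBXT and SOX6 (-0.70) among 23 of 28 lower genes and none called. The type I interferon list stood at -0.38, and at 0.03 without the narrow arrays after quantile normalization. Its 1 called gene was USP18 at -1.74 (SE 0.28). Hypoxia and glycolysis stood at -0.31, but at 0.04 after quantile normalization and 0.16 after scaling to the same SD, with LDHA, lactate dehydrogenase A, at -1.03 and not called. The second CD133+CD15+ array of MUG-CHOR1 weighed on these medians: left out alone, it moved them to -0.41 for housekeeping genes, -0.24 for oxidative phosphorylation, -0.14 for ribosomal proteins, -0.17 for interferon and -0.16 for hypoxia, and the calls of ribosomal proteins and interferon ended.

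Higher medians were found for olfactory receptors (0.20, 312 of 358 positive), microRNA genes (0.17, 1046 genes, 1 called lower), granulocyte markers (0.24), lymphocyte markers (0.24), neural lineage markers (0.26) and NF-kB and inflammatory genes (0.16, 26 of 34 positive), positive under every scaling. Except for that microRNA gene, no member of these 6 lists passed, also when adjusted over the list alone. The olfactory receptor mean was 0.05 to 0.12 above the CD133-CD15- arrays on the first duplicates and 0.15 to 0.49 on the narrow second ones, and the granulocyte mean 0.02 to 0.15 and 0.24 to 0.62. The NF-kB list went the other way, with 0.12 to 0.55 on the first and -0.48 to 0.20 on the second. In a comparison chosen after the values were seen, random lists of the same levels had G2/M medians of -0.66 to -0.40 (95% of 10000 lists) against the measured -1.30. Granulocyte markers, at percentile 92.95, and lymphocyte markers, at 95.36, lay inside the 95% range of such lists. Neural markers, at 97.6, and NF-kB genes, at 99.74, lay above it. Apart from G2/M and G1/S, the lists with lower medians that passed did not lie below the 95% range of such lists: notochord was at percentile 39.8, cholesterol at 10.0, housekeeping at 4.84, interferon at 72.25, ribosomal proteins at 80.21 and oxidative phosphorylation at 80.95, and hypoxia, at 98.1, lay above the 95% range of -0.65 to -0.32. With the narrow arrays left out the notochord list (-0.16) lay at percentile 22.4, and the cholesterol list (-0.36) lay below the 95% range of -0.28 to 0.01, with 16 of 10000 random lists as low. That median was -0.03 in JHC7, with 9 of 19 genes positive, -0.45 in U1 and -0.60 in MUG-CHOR1, and the list did not pass across lines with an estimated correlation (adjusted p = 0.460).

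The other 24 lists did not pass, and 17 of them had a median of the other sign under at least 1 scaling. Their medians were -0.35 for the unfolded protein response, -0.34 for amino acid starvation, -0.31 for p53 targets, -0.30 for heat shock and immediate early genes, -0.27 for histones, -0.23 for Hedgehog, -0.22 for mesenchymal genes, -0.17 for drug transporters, -0.16 for apoptosis regulators, -0.15 for antigen presentation and -0.07 for TGF-beta and BMP targets. They were 0.22 for fibroblast markers, 0.19 for sort antigens, 0.19 for macrophage and monocyte markers, 0.17 for pluripotency and stem cell factors, 0.14 for endothelial markers, 0.13 for Wnt, 0.10 for epithelial genes, 0.09 for erythroid markers, 0.06 for small nucleolar RNAs, 0.05 for Notch, 0.02 for cartilage matrix, 0.00 for receptor tyrosine kinases and 0.00 for mitochondrially encoded genes. Only DCN among fibroblast markers and BIRC5, or survivin (-1.30), among apoptosis regulators were called, and BIRC5 is also on the G2/M list. Adjusted over the list alone, 4 histones, 2 p53 targets, 1 cartilage gene and 1 Hedgehog gene were lower and 1 epithelial, 1 mitochondrially encoded and 1 heat shock gene were higher. Median and mean differed in sign for cartilage matrix, epithelial, Wnt, receptor tyrosine kinase and small nucleolar RNA lists, and for cartilage matrix and receptor tyrosine kinases the test followed the mean. Among stem cell factors, MSI1, an RNA-binding protein of neural progenitors, was at 0.63 (adjusted p = 0.138) and the drug efflux pump gene ABCB1 at -0.90 (adjusted p = 0.125).

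Within JHC7, CD133+CD15+ cells had more IGFBP5 (log2 3.02, SE 0.44, adjusted p = 0.0180, n = 2 and 2 arrays), AMBN (2.51, SE 0.30, adjusted p = 0.0058) and DLX3 (2.26, SE 0.37, adjusted p = 0.0390), and more FABP7, a fatty acid-binding protein gene of brain (1.16, SE 0.19). KRT4, a keratin of squamous epithelia, fell by 2.74 (SE 0.30), LINC00624 by 2.70 (SE 0.31), TMEM207 by 2.64 (SE 0.36), LGALS17A by 2.50 (SE 0.29) and RNU5F-1, a U5 small nuclear RNA gene, by 3.07 (SE 0.39). In all 19 genes passed, 4 higher and 15 lower, and 9 of them also passed across lines. Without the narrow arrays 211 passed, the 19 among them, and 5 passed after quantile normalization, 4 after scaling to the same SD, 1 without a variance trend and 0 in limma on the 4 arrays of the line alone (1533 at an unadjusted p under 0.05). Single arrays moved the count to 498 genes without its first CD133+CD15+ duplicate, 4 and 1 without its CD133-CD15- arrays, 10 without either U1 CD133+CD15+ array, 12 without either U1 CD133-CD15- array, 30 without the second CD133+CD15+ array of MUG-CHOR1 and 9 without either CD133-CD15- array of MUG-CHOR1.

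Within U1, CD133+CD15+ cells had more BEX1, a brain-expressed X-linked gene (log2 2.81, SE 0.30, adjusted p = 0.00577, n = 2 and 2 arrays), DCN (1.89, SE 0.23, adjusted p = 0.0102), the neurofilament gene NEFL (1.88, SE 0.29), LINC01602 (1.50) and SST, which encodes somatostatin (1.49, SE 0.23). EPYC, a proteoglycan gene of cartilage, fell by 2.95 (SE 0.40), CPM, carboxypeptidase M, by 2.55 (SE 0.31), the sodium-calcium exchanger gene SLC24A3 by 2.50 (SE 0.37), the fatty acid elongase gene ELOVL2 by 2.40 and SLC16A14 by 2.35. In all 13 genes passed, 5 higher and 8 lower, and 4 of them also passed across lines. Without the narrow arrays 251 passed, the 13 among them, and after quantile normalization or scaling to the same SD 1 passed. Left out singly, the arrays gave 2 genes without its second CD133+CD15+ duplicate, 0 in limma without either of its CD133-CD15- arrays (997 and 642 at an unadjusted p under 0.05), 20 without the second CD133+CD15+ array of JHC7, 3 without either CD133-CD15- array of JHC7, 23 and 24 without the CD133+CD15+ arrays of MUG-CHOR1 and 5 without either of its CD133-CD15- arrays.

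Within MUG-CHOR1, 2 genes passed, both lower in CD133+CD15+ cells: HHLA2, an immune checkpoint ligand gene of the B7 family (log2 -2.68, SE 0.34), and MAMDC2 (-1.99, SE 0.26), each with an adjusted p of 0.0386 (n = 2 and 2 arrays). At an unadjusted p under 0.05 there were 2816 genes. Without the narrow arrays 10 genes passed, 2 higher and 8 lower, and neither HHLA2 nor MAMDC2 was among them, and no gene passed in limma after quantile normalization (2412 at an unadjusted p under 0.05). Leaving out 1 array gave 7876 genes without its first CD133+CD15+ duplicate, 1 without its second, 2 without its first CD133-CD15- array, and 0 in limma without its second (741 at an unadjusted p under 0.05) or without any of the 8 arrays of JHC7 and U1 (1982 to 3492).

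Whether the sort effect differed between lines was tested directly. The 6 genes with the smallest p included LGALS17A (adjusted p = 0.128), at -2.50 in JHC7, 0.26 in U1 and 0.47 in MUG-CHOR1, and BEX1 (adjusted p = 0.128), at 0.25, 2.81 and -0.19. LINC00624 and KRT4 had an adjusted p of 0.133. MATN3, which encodes the cartilage matrix protein matrilin 3, was at -2.21 in JHC7, 0.71 in U1 and 0.16 in MUG-CHOR1, and HAS2, a hyaluronan synthase gene, at 0.47, -2.24 and -0.39, with adjusted p of 0.187 and 0.189. None of the 22395 genes passed in limma, and 584 did at an unadjusted p under 0.05, so with all arrays the lists of genes called within each line are not shown to differ. No gene was called within both JHC7 and U1, but with only 19 and 13 of 22395 genes called there this does not show that the lines differ. Without the narrow arrays 46 genes passed, among them all of these 6 but LINC00624. With 1 array left out there were 776 genes, all 6 among them, without the first CD133+CD15+ duplicate of MUG-CHOR1, 5 without that of JHC7 and 0 in limma without any of the other 10 (388 to 966 at an unadjusted p under 0.05).

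As background, the lines were compared with each other over both sorts. JHC7 had the highest CA3, or carbonic anhydrase III (log2 6.42 above the mean of the other lines, adjusted p = 1.72e-07, n = 4 arrays per line), and MMP1, a collagenase gene (5.66, adjusted p = 3.73e-07), then RFPL4AL1 (5.24), BST2, or tetherin (4.32), and SERPINB1 (4.13). U1 had the highest matrix genes LUM, or lumican (4.72), and EPYC (4.56), the adhesion receptor gene ADGRG2 (4.66), the actin-severing gene SCIN (4.31) and the cancer-testis gene MAGEC2 (4.15). MUG-CHOR1 had the highest MXRA5 (4.33, adjusted p = 0.000305), RNASE2CP (3.54), EXOC1L (3.29), the protease inhibitor gene SPINT2 (3.28) and the interferon-induced gene IFITM2 (3.23). In all 2039 genes passed between lines, 4858 at an unadjusted p under 0.05. Without the narrow arrays 7840 passed, and single arrays moved the count by over 1.5 times: 5253 and 4162 without the first and second CD133+CD15+ arrays of MUG-CHOR1, 1206 and 1228 without its CD133-CD15- arrays, 1208 and 1174 without those of JHC7, and 1284 and 1233 without those of U1.

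**Figure D4:**
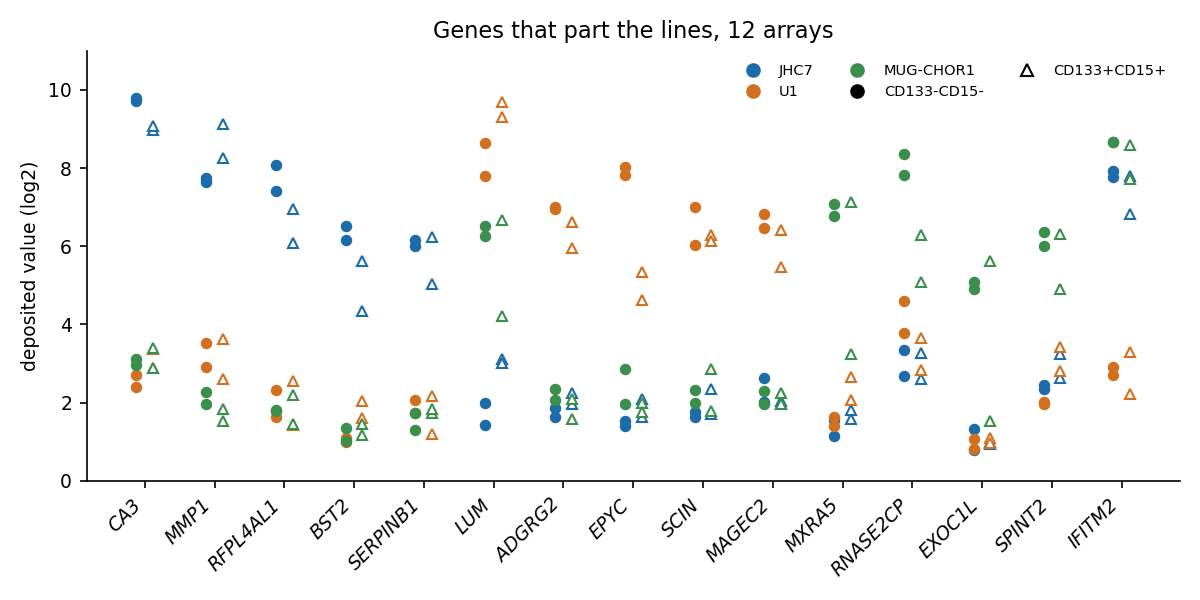
Deposited values (log2) of the 15 genes with the largest excess in 1 line, on the 12 arrays, coloured by line, with filled circles for CD133-CD15- and open triangles for CD133+CD15+ arrays. In the CD133-CD15- cells CA3 has a mean of 9.75 in JHC7 against 2.56 in U1 and 3.04 in MUG-CHOR1.

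The within-line differences of all 22395 genes correlated between lines at 0.542 for JHC7 and U1, 0.640 for JHC7 and MUG-CHOR1 and 0.566 for U1 and MUG-CHOR1, and 58.8% of genes had the same sign in all 3 lines. These are correlations across genes, which are not independent replicates. Among 100 splits of the arrays within lines, those that changed the groups of a line of the pair gave at most 0.498, 0.580 and 0.494. The share of genes with the same sign was at most 55.0% in the other splits. Each line can be divided in only a few ways, so the 100 splits repeat a few correlations, many with the sign turned. These highest values came from splits that kept the narrow arrays in the same group. The other splits also mix or swap the sorts in at least 1 line. The ranking therefore cannot exclude chance or separate the sorts from the narrow arrays. Without the narrow arrays the correlations of the real groups were 0.122, 0.187 and 0.269, and the share was 34.1%. Genes at high levels fell on the narrow arrays. The 817 genes at a mean of 6 to 8, with only 122 genes above them, had medians of -0.81, -0.61 and -2.23 on the second duplicates. On the first duplicates their medians were -0.15, -0.20 and -0.14, each time in JHC7, U1 and MUG-CHOR1. After centring each array on its median, the median difference of all genes moved from -0.02 to -0.14, and relative to that shift the G2/M median was -1.29.

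**Figure D5:**
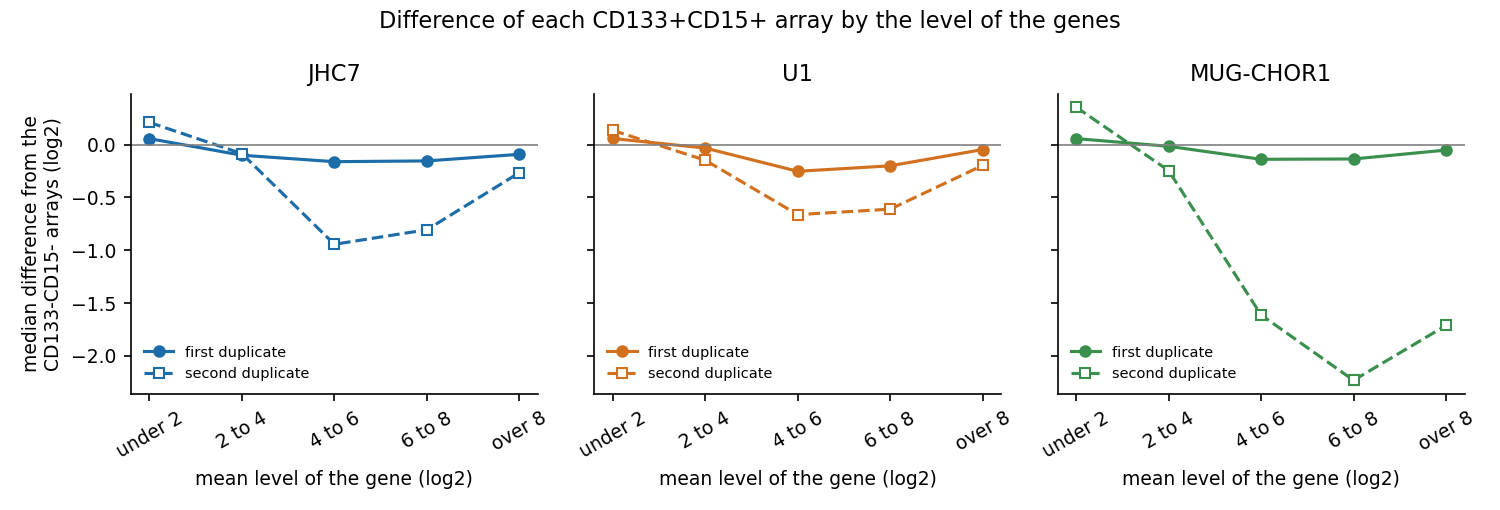
Median difference (log2) of each CD133+CD15+ array from the CD133-CD15- arrays of its line, by the mean level of the genes (log2), 1 panel per line. Second duplicates (dashed lines) fall to -0.94 in JHC7, -0.66 in U1 and -2.23 in MUG-CHOR1, and first duplicates (solid lines) fall no lower than -0.25.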

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

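All tests weighed in this part were chosen only after the result was seen.

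The second CD133+CD15+ array of MUG-CHOR1 stood apart from the other CD133+CD15+ arrays by its mean correlation with the other 11 arrays, 0.7857 (next lowest 0.873), with a gap of 0.665 of the range, past Dixon's critical value for 6 arrays. It was the only 1 of 8 array measures past that value, and chance marks about 1 in 20 such groups. Its SD over probe sets was 1.28, and the JHC7 and U1 arrays of the same number had the next lowest SDs.

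The narrow spread of the second CD133+CD15+ duplicates was weighed against 3 explanations. A property of the CD133+CD15+ cells as the whole cause would give a like loss on the first duplicates. Their steepest slope of the difference on the level of the genes was -0.09001, against -0.204 to -0.497 on the second duplicates, which argues against it. A weaker loss shared by the sort stays open. The slopes of the first duplicates were negative in each line, at -0.065 in JHC7, -0.090 in U1 and -0.055 in MUG-CHOR1. Their SDs also lay below those of both CD133-CD15- arrays of their line. Arrays of another line under these labels are argued against as well, since all 3 arrays correlated best with their own line over the 500 genes that part the lines (0.739, 0.811 and 0.390, with -0.063 the highest value for another line). Less or poorer RNA, or weaker labelling, stays open. At least 87.09% of the 4936 genes at log2 4 to 8 lay below the CD133-CD15- arrays on each of the 3 arrays. On the first duplicates 66.3 to 72.6% did, but this restates the narrow spread. The labels give the same protocol amount of RNA, 500 ng, for every array. Measured amounts and RNA quality per array are not given in the sources used here.

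The lower cell cycle genes in CD133+CD15+ cells were weighed next. Signal lost on the second CD133+CD15+ duplicates is argued against as the whole cause, since without these arrays the G2/M median was -0.9968, below the 95% range of random lists of the same levels, -0.24 to -0.08. A loss that depends on the level of a gene is argued against as well: on the remaining arrays after quantile normalization the median was -0.8837, below the lowest of the random lists, -0.22. Fewer cycling cells, or less cell cycle transcript per cell, in the CD133+CD15+ sort stays open. The highest of the 6 medians of both lists in the 3 lines on the first duplicates was -0.4746, and all 6 lay below the ranges of their random lists, which restates the pattern for each line and tests no source of it. Those data cannot separate a smaller share of cycling cells from a lower level per cell, and how the sort gates treated large or dividing cells stays untested.

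The absence of a PROM1 difference between populations sorted on CD133 was weighed last. A difference hidden by the narrow arrays and a probe set that responds poorly cannot be told apart from equal transcript levels. Without those arrays PROM1 differed by 0.1331 (SE 0.14), and over all 12 arrays it reached at most percentile 93.86 of the olfactory receptor genes, a level at which a transcript present in few copies could look the same. CD133 was sorted as a surface protein, and protein levels were not analysed here.

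Of 100 splits of the arrays within lines, only the real one gave as many genes across lines (76 against at most 1 in the others). The other splits mix or swap the sorts in at least 1 line. A difference between sorts then widens their spread or cancels, so the splits cannot exclude chance. Leaving out 1 array moved this count from 0 to 9114. Between lines, only the real split of 100 gave as many genes (2039 against at most 751). The same limit holds there, since the other splits mix the lines. Among the 29746 probe sets with no or several symbols, 2 without a symbol were called higher across lines and none lower, with 5546 at an unadjusted p under 0.05 in limma. Their log2 differences were 1.22 (SE 0.13) and 3.14 (SE 0.32), each with an adjusted p of 0.0369, and both were higher in all 3 lines, the stronger by 2.95 in JHC7, 3.79 in U1 and 2.69 in MUG-CHOR1.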

How the results depend on the processing

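Tests that leave out the second CD133+CD15+ duplicates, scale arrays to the same SD or cross the duplicate numbers of JHC7 were chosen only after the result was seen. The counts stayed within 1.5 times of the reported ones for every named probe set, the mean of probe sets, a robust variance and the 2-fold threshold on adjusted p. The 15 genes that part the lines kept direction and call in all 374 recomputed values, the 52 calls of named genes between the sorts kept direction in all 1519 and the call in 777, and for 131 differences of named genes that were not called 360 of 4153 values passed. Of 969 values of the 39 lists, 835 kept direction and side, 83 lost the call, 38 gained it and 13 turned. Genes near background, such as PROM1, limit what the arrays can show. For the values given next the cause was not tested, except that fewer arrays or genes enter where some are left out. Endothelial, erythroid, granulocyte, lymphocyte, macrophage and neural markers had too few genes above the median level to be run there. Where a group keeps 1 array, that array is assumed to vary like the other groups.

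Counts are given for across lines, JHC7, U1 and MUG-CHOR1, where they moved. Quantile normalization gave 0, 5, 1 and 0 (3767 and 2412 at an unadjusted p under 0.05 where limma gave 0), scaling to the same SD 0, 4, 1 and 0 (3831 and 2291), no variance trend 0, 1, 3 and 0 (5676 and 2733), and all probe sets 2, 0, 3 and 1 (3071 for JHC7). Genes above the median level gave 224 across lines, 5 in U1 and 0 in MUG-CHOR1 (1739), array weights 205, 188 and 0 (1492), and an unadjusted p with a 2-fold change 1010, 758, 671 and 1602, with 516 for the difference between lines. Across lines there were 126 genes after centring on the median, 4239 with averaged duplicates, 157 in the additive model, 6291 with a random block (consensus correlation -0.298), 0 without a line term (5133) and 0 without JHC7, U1 or MUG-CHOR1 (3790, 3029 and 4299). On the 4 arrays of a line JHC7 gave 0 (1533), U1 7 and MUG-CHOR1 0 (1117). A block of duplicate numbers gave 7 in U1, 1 in MUG-CHOR1 and 1 for the difference between lines, and with the JHC7 numbers crossed the block gave 290 across lines, 4 in MUG-CHOR1 and 4 for that difference.

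Without the second CD133+CD15+ duplicates the counts were 426, 211, 251 and 10, with 46 for the difference of the sort effect and 7840 between lines. After quantile normalization as well they were 297, 179, 233, 5, 52 and 8117, and leaving out only those of JHC7 and MUG-CHOR1 they were 225, 63, 587, 1, 22 and 6778. Leaving out 1 array gave 0 to 9114 across lines, 1 to 498 in JHC7, 0 to 24 in U1, 0 to 7876 in MUG-CHOR1, 0 to 776 for the difference of the sort effect and 1174 to 5253 between lines. The first CD133+CD15+ array of MUG-CHOR1 gave the highest value of each but JHC7, whose own first array did, and U1, where the second of MUG-CHOR1 did.

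No list passed with an estimated correlation: the 15 medians were -1.30 for G2/M, -1.03 for G1/S, -0.78 for housekeeping, -0.60 for cholesterol, -0.49 for notochord, -0.40 for oxidative phosphorylation, -0.38 for interferon, -0.32 for ribosomal proteins, -0.31 for hypoxia, 0.16 for NF-kB, 0.17 for microRNAs, 0.20 for olfactory receptors, 0.24 for granulocytes, 0.24 for lymphocytes and 0.26 for neural markers. In fry only G2/M and G1/S passed. Calls lost after quantile normalization were notochord (-0.155), hypoxia (0.039), oxidative phosphorylation (-0.080), ribosomal proteins (-0.101), interferon (-0.164), housekeeping (-0.282), granulocytes (0.145), lymphocytes (0.193) and neural markers (0.206), and small nucleolar RNAs (0.083) gained one. Centring ended that of hypoxia (-0.426).

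Above the median level the calls of notochord (-0.530), oxidative phosphorylation (-0.469), ribosomal proteins (-0.339), interferon (-0.507), cholesterol (-0.608) and housekeeping genes (-0.780) ended, mitochondrially encoded genes (0.0013), small nucleolar RNAs (-0.192) and fibroblasts (0.219) passed, and the test of hypoxia (-0.345) turned. With the duplicate block the unfolded protein response (-0.348) and histones (-0.267) passed.

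Without JHC7 the call of NF-kB (0.055) ended and the unfolded protein response (-0.455) passed. Without U1 those of hypoxia (-0.254), NF-kB (0.151) and neural markers (0.183) ended, and p53 targets (-0.311), histones (-0.745), small nucleolar RNAs (0.161) and macrophages (0.209) passed. Without MUG-CHOR1 those of hypoxia (-0.198) and interferon (-0.222) ended and fibroblasts (0.195) passed.

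Without the second CD133+CD15+ duplicates hypoxia (-0.113), oxidative phosphorylation (-0.122), ribosomal proteins (-0.073), interferon (-0.027) and granulocytes (0.075) lost the call. Small nucleolar RNAs (0.111, list mean -0.42 to 0.40 over the lines) and fibroblasts (0.218) gained it, and heat shock (0.095) turned and passed as higher. After quantile normalization as well, notochord (-0.123), hypoxia (-0.027), oxidative phosphorylation (-0.058), interferon (0.029), housekeeping (-0.156), granulocytes (0.044) and neural markers (0.103) lost it, and small nucleolar RNAs (0.103) and fibroblasts (0.157) gained it. Drug transporters (0.080), mesenchymal genes (0.139), the unfolded protein response (0.118), heat shock (0.244) and TGF-beta and BMP targets (0.145) turned and passed as higher. There too the test of ribosomal proteins turned while the median stayed negative (-0.0064).

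After scaling to the same SD, notochord (0.047) and hypoxia (0.163) turned without passing. Mesenchymal genes (0.231) and heat shock (0.275) turned and passed as higher (camera, adjusted p = 0.0419 and 0.00224). For ribosomal proteins only the direction of the test turned, with a median still negative (-0.052). Oxidative phosphorylation (-0.073), interferon (-0.154), microRNAs (0.042), olfactory receptors (0.071), housekeeping (-0.174) and lymphocytes (0.171) then lost the call, and stem cell factors (0.128), mitochondrially encoded genes (1.68) and fibroblasts (0.377) gained it.

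Leaving out 1 array, medians ranged from 0.048 to 0.226 for NF-kB, which lost its call without the first CD133+CD15+ array of any line or the second CD133-CD15- array of JHC7 or MUG-CHOR1. Hypoxia (-0.440 to -0.164) lost it without the second CD133+CD15+ array of JHC7 or U1, either CD133-CD15- array of JHC7, or the first of U1 or MUG-CHOR1. Interferon (-0.623 to -0.173) lost it without the second CD133+CD15+ array of JHC7 or MUG-CHOR1, ribosomal proteins (-0.428 to -0.138) without that of MUG-CHOR1 and neural markers (0.187 to 0.351) without its first. The unfolded protein response (-0.606 to -0.109) and amino acid starvation (-0.593 to -0.087) gained a call without the first CD133+CD15+ array of JHC7 or MUG-CHOR1 or the second CD133-CD15- array of U1 or MUG-CHOR1. Heat shock (-0.549 to 0.011) and erythroid markers (0.068 to 0.208) gained one without the first CD133+CD15+ array of MUG-CHOR1, and macrophages (0.075 to 0.276) without that of JHC7. Histones (-0.362 to -0.120) did so without the second CD133+CD15+ array of JHC7 or the second CD133-CD15- array of U1 or MUG-CHOR1, and small nucleolar RNAs (-0.016 to 0.144) without the second CD133+CD15+ array of JHC7 or MUG-CHOR1 or the second CD133-CD15- array of U1. Fibroblasts (0.153 to 0.305) did so without the second CD133+CD15+ array of U1 or MUG-CHOR1. The calls of housekeeping genes (-0.409), oxidative phosphorylation (-0.239), hypoxia (-0.164) and microRNAs (0.103) held without the second CD133+CD15+ array of MUG-CHOR1, but the medians moved by over 1.5 times, as that of interferon (-0.623) did without its first.

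For lists called neither with all arrays nor with 1 left out, the medians that moved by over 1.5 times ranged from -0.350 to -0.063 for Hedgehog, -0.380 to -0.029 for mesenchymal genes, -0.311 to -0.0031 for drug transporters, -0.378 to -0.155 for p53 targets, -0.278 to -0.131 for apoptosis regulators, -0.247 to -0.054 for antigen presentation, -0.204 to -0.017 for TGF-beta and BMP targets and -0.094 to 0.077 for cartilage matrix. They ranged from -0.084 to 0.034 for receptor tyrosine kinases, -0.034 to 0.037 for mitochondrially encoded genes, 0.018 to 0.188 for Notch, 0.057 to 0.184 for epithelial genes, 0.060 to 0.293 for endothelial markers, 0.064 to 0.150 for Wnt, 0.079 to 0.261 for sort antigens and 0.103 to 0.246 for stem cell factors.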

Other observations

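The tests on the 9 arrays that remain without the second CD133+CD15+ duplicates, by line or over them, the counts of random lists and the comparisons of list means by duplicate were chosen only after the result was seen, while values with all arrays come from the comparisons fixed before. TBXT, MKI67, KIF20A, DCN, EPYC, LUM, COL1A1, VCAM1 and ND6 are named by the rule, and the other genes were chosen after their values were seen.

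On the 9 arrays that remain without the second CD133+CD15+ duplicates, 5 inflammatory genes were higher in CD133+CD15+ cells on average over the lines. Of 34 genes of the NF-kB and inflammatory list 5 rose, 6 when adjusted over the list alone, with a median of 0.34 (camera, adjusted p = 2.02e-09, and adjusted p = 0.289 with an estimated correlation, against 6.30e-11 to 0.654 over the alternatives). They were TNFAIP3, an inhibitor of NF-kB signalling (log2 1.00, SE 0.19), the adhesion molecule gene VCAM1 (0.87, SE 0.15), NFKBIA, which encodes an inhibitor of NF-kB (0.82, SE 0.18), the stromelysin gene MMP3 (0.74, SE 0.15) and the chemokine gene CCL2 (0.62, SE 0.11), n = 3 and 6 arrays. By line MMP3 was at 1.99 in JHC7 against 0.02 in U1 and 0.22 in MUG-CHOR1, and CCL2 at 1.82 in U1 against 0.14 in JHC7 and -0.09 in MUG-CHOR1, and the test of a difference between lines passed for CCL2 (adjusted p = 0.0271) but not for MMP3 (adjusted p = 0.0879). With all arrays none of the 5 passed, and TNFAIP3 stood at 0.26 and NFKBIA at 0.25. The list mean was 0.12 to 0.55 above the CD133-CD15- arrays on the first duplicates and between -0.48 and 0.20 on the second. None of 10000 random lists of the same levels had a median as high as 0.34, but this was not particular to the list. None was as high as the heat shock and immediate early genes (0.10) or the small nucleolar RNAs (0.11). As high as the unfolded protein response (0.03) were 2, as the fibroblast markers 5 and as the mesenchymal genes (0.08) 6. The small nucleolar RNA mean went opposite ways between lines, from -0.42 to 0.40 on the first duplicates.

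On the same 9 arrays 3 of 14 fibroblast markers rose, and 5 of the 14 had a negative difference. The called genes were LUM (log2 1.05, SE 0.20), COL1A1 (0.82, SE 0.17) and DCN (0.74, SE 0.11), all genes of extracellular matrix, with COL1A1 at 0.12 and DCN at 0.16 in JHC7 and LUM at 0.29 in MUG-CHOR1 and a list median of 0.22 (adjusted p = 0.00945, and adjusted p = 0.315 with an estimated correlation, against 0.00859 to 0.524 over the alternatives). With all arrays only DCN passed, with LUM at 0.56 (adjusted p = 0.331) and COL1A1 at 0.67 (adjusted p = 0.158). The cartilage matrix list did not pass, with a median of -0.08 and 13 of 22 genes negative. Of its genes EPYC fell by 0.95 (SE 0.20) and PRG4 rose by 0.71 (SE 0.10) on average. By line EPYC was at -2.59 in U1, 0.17 in JHC7 and -0.44 in MUG-CHOR1 (adjusted p = 0.0799 for a difference between lines), and PRG4 at 2.08 in JHC7, 0.01 in U1 and 0.05 in MUG-CHOR1 (adjusted p = 0.0183). LUM is also among the genes highest in U1. SOD3, the extracellular superoxide dismutase gene, was at 1.16 (SE 0.15) and ANKRD1 at 1.06 (SE 0.15), but with all arrays neither passed, at 1.03 (adjusted p = 0.110) and 0.82 (adjusted p = 0.174). TBXT fell by 0.69 (SE 0.13) and the desmosome gene DSG2 by 0.60 (SE 0.14), the only called members of the notochord and chordoma list. DSG2 just passed (adjusted p = 0.0499) and did not after quantile normalization of the same arrays (adjusted p = 0.106).

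Of the mitochondrially encoded genes, ND6 differed by 1.85 (log2, SE 0.37, adjusted p = 0.0532) with all arrays, higher on all 6 CD133+CD15+ arrays, and by 1.45 (SE 0.27) on the 9 remaining arrays, where it passed. The other 7 lay between -0.27 and 0.11. ND6 is the mitochondrial protein gene read from the other strand than the rest.

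Within single lines the 9 arrays gave RAB27B at 3.02, COL12A1 at 2.97, TAC3 at 2.73 and PRG4, or lubricin, at 2.08 in JHC7, where the test of the difference between lines also passed for each. With all arrays none of these 4 was called in JHC7, with RAB27B at 1.99, COL12A1 at 2.00, TAC3 at 2.05 and PRG4 at 1.25. In U1, AMTN was at 3.38, ANKRD1 at 2.12 and CCL2 at 1.82, of which AMTN and CCL2 passed that test, and in MUG-CHOR1 KIF20A was at -3.11, MKI67 at -2.75 and TOP2A, a topoisomerase of dividing cells, at -2.63. With all arrays AMTN (2.66), ANKRD1 (1.23) and CCL2 (0.79) were not called in U1, nor KIF20A (-2.79), MKI67 (-3.21) and TOP2A (-3.41) in MUG-CHOR1. The spread behind these values came from the CD133-CD15- duplicates alone, and each lone CD133+CD15+ array was assumed to vary like them.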
